A study of Arabidopsis thaliana with 18 samples.

How the data were processed

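Small RNA libraries were made from flowers of Arabidopsis thaliana, ecotype Columbia, grown in long days. Per the labels, total RNA was extracted with phenol and made into standard Illumina small RNA libraries. The tables deposited by the authors, 1 per library, give distinct sequences with their count, the number of reads of that sequence, with no header and no normalisation. Per the submitters' processing notes, reads were matched with Bowtie to TAIR10; the Bowtie version and settings are not given in the sources used here. Tested on the tables, the lowest count was 2 in every library, so sequences read once are missing, and sequences were 10–101 nt long. Of 1894546 distinct sequences of 18–26 nt, 1894536 matched the TAIR10.1 reference without mismatch, practically all at a single place. Small RNAs of repeated loci, multi-copy miRNAs among them, are therefore missing or reduced, and table totals (3314877–6621165 reads per library) are not library depths.

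The labels gave 6 groups with 17 libraries: wild type, rtl2, 35S-RTL2, dcl234 and 35S-RTL2_dcl234 with 3 each, and 35S-RTL1 with 2. For 1 more library the title and the genotype label name different constructs; it entered no comparison and is described by single values. Libraries came from lanes 1 and 2, with both 35S-RTL1 libraries in lane 1. Nothing in the labels states that replicates came from separate plants or cultures, so p-values measure the spread among samples, which may be technical. Correlations of deviations from the group means paired libraries by replicate number (every pair over 0.1) for miRNA families, in rtl2 against wild type (0.113–0.156) and 35S-RTL2_dcl234 against dcl234 (0.151–0.264). The same held for families between groups not compared directly, rtl2 and dcl234 (0.195–0.244) and 35S-RTL2 and dcl234 (0.255–0.341).

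Sequences were matched to the reference with a Python 3.11.15 script (numpy 2.4.6, pandas 2.3.3, numba 0.67.0), checked on 80 of 80 sequences against a direct search. The counts used were 23–24-nt reads in 500-nt windows (called 24-nt loci, which can hold miRNA genes), 21–22-nt reads over 36575 genes on either strand, and miRNA families. Gene counts include reads of any miRNA gene that lies within the gene, also where no overlap is named below. Families were 19–25-nt reads sharing their first 18 nt with 1 of 428 annotated mature miRNAs, which formed 210 families. A family with several genes is counted practically only by sequences that match a single place, which may leave out its main mature sequence. Features with at least 10 counts in at least 3 libraries were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, two-sided, a single fit of all 17 libraries, Benjamini-Hochberg adjustment, false discovery rate of 0.05). The SE given for a log2 change is its absolute value divided by the square root of the F statistic. Libraries were scaled by TMM (trimmed mean of M values) over miRNA families, because 24-nt siRNAs, most of the reads, were what the genotypes were meant to alter. This scale takes miRNA families as a whole to be unchanged, so a general shift of miRNAs cannot show on it. "Rose" and "fell" are used only for features past that rate; normalised counts are counts scaled to the mean library in that way. Where a group had 0 counts, folds are lower bounds against a floor of 3 counts over the group, and medians are also given with such features at their bound. Intervals and floors cover counting error only. They do not cover sequences read once, which are missing, so folds over all reads could lie below these bounds.

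The 7 comparisons were rtl2, 35S-RTL2, 35S-RTL1 and dcl234 each against wild type, 35S-RTL2_dcl234 against dcl234, the difference between the changes made by 35S-RTL2 in both backgrounds, and 35S-RTL1 against 35S-RTL2. Groups, comparisons, tests, lists and the rule for naming features were fixed before the data were examined. The rule named the 4 largest changes per direction, comparison and kind (3 for the difference of changes) among those past the rate. They needed a mean of at least 50 counts in the higher group and an absolute log2 change of at least 1. All libraries of one group had to lie above all of the other, which was not asked for the difference of changes. Adjacent windows changed alike count as 1 locus, given by its most changed window. The most abundant members of each list were named too.

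The 17 lists were the ta-siRNA loci, PPR/TPR siRNA genes (pentatricopeptide and tetratricopeptide repeat genes), other miRNA-triggered siRNA genes, small RNA pathway genes, windows in and 1 kb around RdDM-regulated genes (RNA-directed DNA methylation), conserved miRNAs, young miRNAs, DCL4-made miRNAs, phosphate-starvation miRNAs, copper-responsive miRNAs, flower development miRNAs, siRNA-trigger miRNAs, the pollen miRNA miR845, pericentromeric windows (within 3 Mb of the centromere), chromosome arm windows, windows over protein-coding genes and intergenic windows. Lists were tested with fry (limma 3.58.1, two-sided, adjusted over the lists of a comparison), which asks whether members move on balance one way and does not compare them with other features; camera with an estimated correlation, which does compare, was the alternative. Single values were compared by two-sided exact permutation tests, which cannot go below p = 0.10 with 3 libraries against 3 or 2 against 3.

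Alternatives were DESeq2 1.42.0 with its own size factors, total matched 18–26-nt reads as the scale, TMM over the tested features, no filter, the replicate number as a block, lane as a covariate, fits of only the groups compared, 1000-nt windows, counts split over matching places, 20–22-nt reads, exact mature miRNAs, camera, and leaving out each library. A minimum of 4 reads per sequence was added after seeing the data. Recovery was measured in counts simulated for all 17 libraries from the wild-type means and the spread of these data. For 3 libraries against 3, log2 changes of 1 were recovered in 13.3% of windows, 22.2% of genes and 50% of families. For 2 against 3 these were 3.1%, 4.3% and 40%. Changes of log2 2 were recovered in 68%, 68.5% and 100%, and in 56.1%, 60.2% and 100% for 2 against 3. These shares hold at wild-type abundance only. They do not apply to comparisons within dcl234 background, since dcl234 kept 5.77% of the wild-type window counts. A list of windows over transposons was planned but the annotation at hand holds none, so it was left out. Figures were drawn with matplotlib 3.10.9, and exact tests used scipy 1.17.1.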

Results

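The small RNAs of flowers were compared among 6 genotypes that differ in a pair of RNase III-like genes, RTL1 and RTL2, and in the Dicer-like enzymes that cut siRNAs. The mutant dcl234 lacks DCL2, DCL3 and DCL4, and the constructs 35S-RTL1 and 35S-RTL2 place a gene behind the strong 35S promoter. Tables held 4531835–5531669 reads per wild-type library, 4874669–5827203 in rtl2, 5081822–6621165 in 35S-RTL2, 4569098 and 5243949 in 35S-RTL1, 3553521–3766473 in dcl234 and 3314877–4173708 in 35S-RTL2_dcl234. In every case named below as a largest change, except for the difference of changes, all libraries of one group lay above all of the other. Where a named locus spans several windows, its counts are those of its most changed window. Over RTL2 (AT3G20420, chromosome 3, 7119191–7121023 in the TAIR10.1 reference, used throughout), 21–22-nt reads reached 191700 ± 12100 normalised counts (mean ± SD, n = 3) in 35S-RTL2. They were at 6.53 ± 7.93 in wild type. They reached 160 ± 54.8 in 35S-RTL2_dcl234, against 5.46 ± 1.48 in dcl234 (n = 3 each). Over RTL1 (AT4G15417) they reached 993 ± 44.1 (SD, n = 2) in 35S-RTL1 and at most 0.679 as the mean of any other group. Reads of 23–24 nt over RTL2 were 18120 ± 571 in 35S-RTL2, 98.6 ± 48.0 in 35S-RTL2_dcl234 and 0 in all libraries of the other groups. Over RTL1 they were 530 ± 12.4 in 35S-RTL1 and at most 4.86 elsewhere. These reads identify the constructs only, since DCL2, DCL3 and DCL4 held at most 5.20 counts in any group and RTL2 held few in wild type, so the mutant labels could not be checked in this way.

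**Figure D1:**
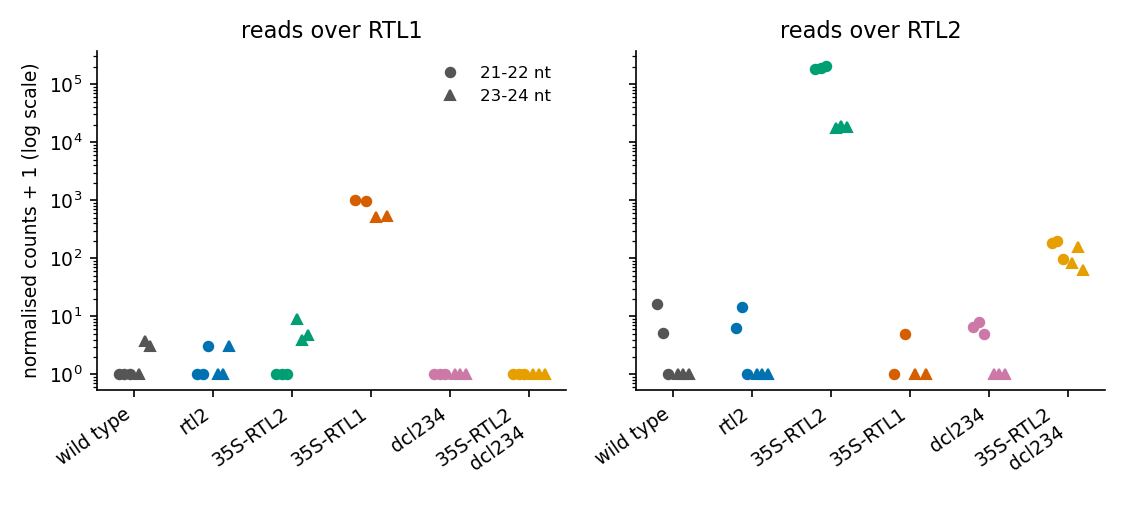
Normalised counts per library (log scale) over RTL1 and RTL2 in each group, with circles for 21–22-nt and triangles for 23–24-nt reads. Reads over RTL2 stand out in 35S-RTL2 and, at a mean of 160 counts of 21–22 nt, in 35S-RTL2_dcl234; reads over RTL1 stand out in 35S-RTL1.

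Reads of 24 nt, the product of DCL3, made up 59.9% ± 1.29 (SD, n = 3) of matched 18–26-nt reads in wild type, 60.6% ± 0.844 in rtl2 and 59.2% ± 0.714 in 35S-RTL2. They were 55.2% ± 0.571 (n = 2) in 35S-RTL1, 12.1% ± 0.132 in dcl234 and 7.30% ± 1.34 in 35S-RTL2_dcl234. Both 35S-RTL1 libraries (54.8% and 55.6%) came from lane 1, where the wild-type libraries held 59.96% and 61.1%. The log2 ratio of 24-nt siRNA to miRNA reads was 2.79 ± 0.112 in wild type, 1.75 ± 0.119 in 35S-RTL1, −1.79 ± 0.0746 in dcl234 and −2.99 ± 0.450 in 35S-RTL2_dcl234. The differences of 35S-RTL1 (−1.04) and dcl234 (−4.58) from wild type and of 35S-RTL2_dcl234 from dcl234 (−1.21) each gave p = 0.10 in a two-sided exact permutation test, the smallest such a design allows. The ratio in rtl2 (−0.11 from wild type) and 35S-RTL2 (0.16) overlapped wild type, with p = 0.2 each in the exact permutation test. Reads of 21 nt, the length of most miRNAs, were 12.2% ± 0.952 in wild type, 18.01% ± 0.113 in 35S-RTL1 and 46.7% ± 3.20 in dcl234. Of matched 24-nt reads outside organelles, structural RNA genes and miRNAs, 63.2% ± 0.709 began with A, the start favoured by the Argonaute AGO4, in wild type, 74.0% ± 0.948 in 35S-RTL1 and 67.5% ± 0.805 in dcl234. Over all 24-nt reads of the tables, per library, these were 62–63.6%, 72.2–73.1% and 54.7–59.4%, so that dcl234 lay above wild type by the former and below it by the latter. Of the former, those beginning with G were 9.03% ± 0.479 in wild type, 2.63% ± 0.0309 in 35S-RTL1, 14.6% ± 0.486 in dcl234 and 22.3% ± 0.516 in 35S-RTL2_dcl234. Mitochondrial reads were 0.775% in rtl2 and 1.15% in wild type, the only class of structural or organelle reads by which rtl2 libraries lay apart from wild type (p = 0.10, exact permutation test, n = 3 each).

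**Figure D2:**
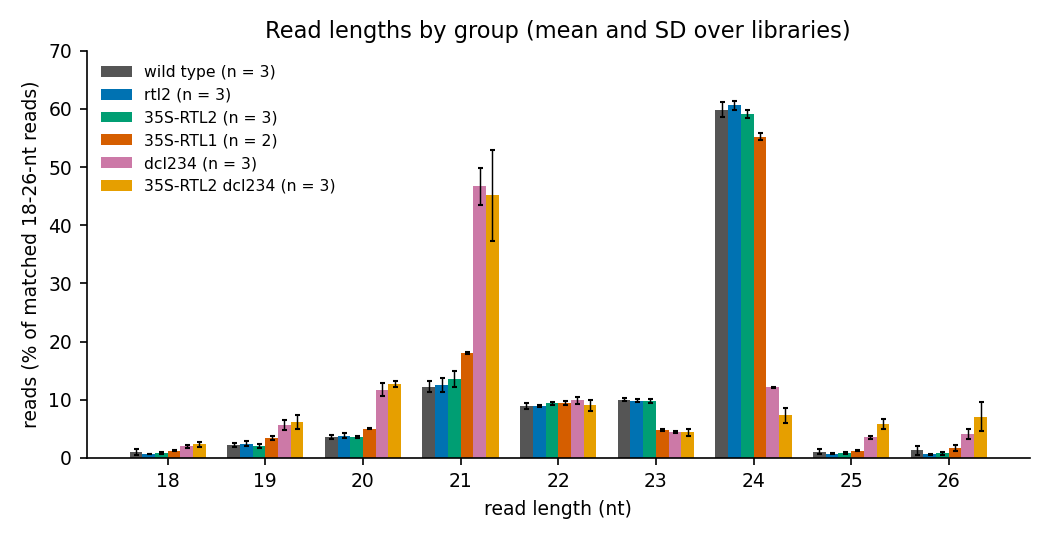
Share of matched 18–26-nt reads (percent) by read length in each group, with bars for the mean and error bars for the SD (n = 3, or 2 for 35S-RTL1). At 24 nt the mean is 59.9% in wild type, 55.2% in 35S-RTL1, 12.1% in dcl234 and 7.30% in 35S-RTL2_dcl234.

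The 35S-RTL1 line was compared with wild type to ask which small RNAs differ with the construct. In 35S-RTL1, 24-nt reads fell to 0 counts in both libraries in UBP6 (AT1G51710, a ubiquitin-specific protease gene; chromosome 1, 19180001–19180500) from 1676 ± 387 (SD, n = 3) in wild type, at least 1220-fold. The same held in AT2G04830 (chromosome 2, 1695501–1696000) from 1379 ± 83.5, at least 1000-fold. Reads were also lost in GH9B12 (AT2G44570, a glycosyl hydrolase gene; chromosome 2, 18396001–18396500) from 1275 ± 89.0, at least 929-fold, and 170 nt from SERPIN1 (AT1G47710; chromosome 1, 17560501–17561000) from 1242 ± 184, at least 905-fold. Other loci rose: in AT1G77100 (chromosome 1, 28966501–28967000) from 11.2 ± 8.46 to 1414 ± 102, a log2 change of 6.88 ± 0.572 (SE). Between genes they rose on chromosome 4 at 2557501–2558500 (7.12 ± 0.776) and 926001–927500 (6.73 ± 0.969) and on chromosome 2 at 17671501–17672000 (6.25 ± 0.831). Of 18004 windows, 493 rose, 14757 fell and 2754 did not pass. The median log2 change was −4.00, or −3.34 with the 4840 windows at 0 set to their bound. Windows of over 1000 wild-type counts (n = 504 windows) had a median of −0.95, and 48.0% of them lay within a factor of 2 of wild type, while windows of 20 to 50 counts had a median of −4.22, or −3.96 at the bound. Of 9001 chromosome arm windows 304 rose and 7615 fell (median −4.69), and of 9003 pericentromeric windows 189 rose and 7142 fell (median −3.31). Camera, which compares a list with other windows, gave an adjusted p = 0.771 for both. Of windows over protein-coding genes 153 rose and 2921 fell, and of intergenic windows 266 rose and 8510 fell; of 8 windows at RdDM-regulated genes 7 fell, or 8 adjusted over the list alone. The split depends on the scale, with 4229 rising and 5965 falling under TMM over the windows (median −1.07). There were 4193 and 6823 with DESeq2 (median −1.26), and total reads gave 974 and 12929 (median −3.34). With lane as a covariate 14937 windows passed, against 15250 without it.

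**Figure D3:**
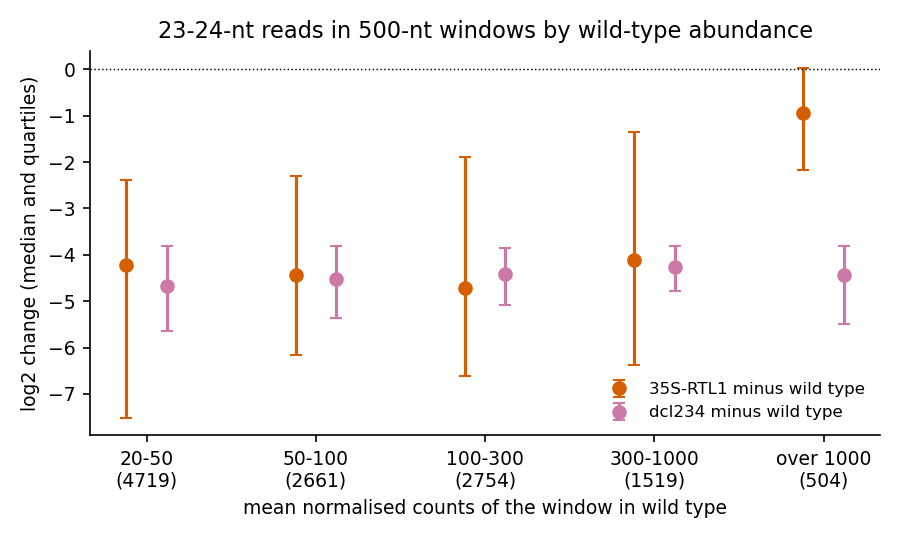
Median log2 change of 24-nt windows (points, with bars from the lower to the upper quartile) in 35S-RTL1 and dcl234 against wild type, by class of wild-type counts; numbers of windows stand under the axis. In windows of over 1000 counts the median is −0.95 in 35S-RTL1 and −4.44 in dcl234.

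Among genes with 21–22-nt reads in 35S-RTL1, the ta-siRNA loci fell, all 7 of 7 tested. TAS1C (AT2G39675) changed by log2 −2.93 ± 0.256 (SE; n = 2 against 3), from 68760 ± 3750 to 9051 ± 1350 counts, TAS2 (AT2G39681) by −2.70 ± 0.235, TAS1A (AT2G27400) by −3.36 ± 0.270 and TAS3 (AT3G17185), whose siRNAs target auxin response factors, by −2.27 ± 0.241. The list's median was −2.93. For it fry gave an adjusted p of 2.05e-09, and the adjusted p = 0.358 with an estimated correlation. Of 13 PPR/TPR siRNA genes 11 fell, with a median of −3.96, or −3.44 at the bound (fry adjusted p 1.12e-07, adjusted p = 0.369 with an estimated correlation). AT1G63130 (−3.24 ± 0.417) and AT1G63150 (−3.14 ± 0.378), named for their abundance, fell less than the median. Among 6 other miRNA-triggered siRNA genes AT5G43740 (−4.00 ± 0.412), AGO1 (−4.44 ± 0.707) and the auxin receptor gene AFB3 (−1.13 ± 0.357) fell and the DNA methyltransferase gene DMT2 rose (2.37 ± 0.677; fry adjusted p 0.000121, adjusted p = 0.866 with an estimated correlation). Of 4 small RNA pathway genes AGO2 (−1.56 ± 0.286), AGO1 and DCL1 (−1.51 ± 0.5) fell (fry adjusted p 3.48e-05; adjusted p = 0.771 with an estimated correlation). For the RdDM-regulated windows fry gave 2.46e-08 (adjusted p = 0.771 with an estimated correlation). Reads rose over ENT6 (AT4G05110, chromosome 4, 2624867–2629058), a gene that overlaps MIR397a, by log2 4.997 ± 0.777. They rose over AT5G55350 (chromosome 5, 22442269–22443437) by 4.42 ± 0.671, over AT1G12665 (chromosome 1, 4312331–4312935) by 4.22 ± 0.627 and over NDL2 (AT5G11790, overlapping MIR5629) by 3.72 ± 0.553. They fell to 0 over AT4G13885 from 152 ± 17.8, at least 111-fold, over the lncRNA genes AT3G06835 (at least 105-fold) and AT1G07233 (at least 98.4-fold), and over PORB (AT4G27440, of chlorophyll synthesis, overlapping AT4G27450; at least 101-fold). Of 1313 genes 60 rose, 707 fell and 546 did not pass (median −1.71, or −1.58 at the bound). There were 153 rises and 533 falls with total reads as the scale (median −1.05) and 184 and 515 with DESeq2 (−0.89). With TMM over genes 692 passed, 76.7% of them falls (−1.01). Of genes 737 passed with lane as a covariate, 435 in a fit of only these groups and 355 with at least 4 reads, against 767.

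Of 100 miRNA families in 35S-RTL1, 21 rose, 27 fell and 52 did not pass (median −0.21, or −0.15 at the bound; 32 rose and 14 fell with total reads as the scale, median 0.42). All 3 copper-responsive miRNAs rose: miR408 by log2 3.83 ± 0.604 (SE), from 670 ± 391 to 9522 ± 3690 counts, miR397 by 5.22 ± 0.845 and miR398 by 3.57 ± 0.346 (fry adjusted p 2.69e-05; adjusted p = 0.358 with an estimated correlation). The largest rise was of miR8170, by 8.43 ± 0.743, from 2.08 ± 3.6 to 984 ± 214, and miR862 rose by 4.07 ± 0.511, a call lost when only exact mature sequences were counted. Of 4 phosphate-starvation miRNAs miR827 (2.03 ± 0.476) and miR2111 (2.78 ± 0.440) rose (fry adjusted p 0.00158; adjusted p = 0.483 with an estimated correlation). Of 3 DCL4-made miRNAs miR822 (−3.17 ± 0.370) and miR869 (−3.70 ± 0.745) fell (fry adjusted p 3.83e-07; adjusted p = 0.358 with an estimated correlation). Other falls were of miR826 (−2.99 ± 0.439), miR858 (−2.50 ± 0.342), a regulator of MYB genes, and miR391 (−2.43 ± 0.460). Among 21 conserved miRNAs 7 rose and 6 fell. Of these miR159, the most abundant, rose by 0.76 ± 0.256 to 279900 ± 41300 counts, and miR396 (−2.26 ± 0.390), which targets growth-regulating factors, and miR403 (−1.10 ± 0.248) fell. Among 37 young miRNAs 6 rose and 9 fell, with miR158 at 0.28 ± 0.307. Among 8 flower development miRNAs miR159 rose and miR172 (−1.73 ± 0.388) and miR160 (−0.98 ± 0.342) fell. Among 6 siRNA-trigger miRNAs miR472 (2.22 ± 0.25) and miR393 (1.57 ± 0.304) rose and miR161 (−2.32 ± 0.322), miR390 (−1.95 ± 0.438) and miR168 (−0.94 ± 0.276) fell. For families with several genes, such changes are those of sequences matching a single place and may not be those of the main mature miRNA. The conserved, young, flower development and siRNA-trigger lists moved in no common direction (fry adjusted p 0.228, 0.202, 0.153 and 0.329), but upward with total reads as the scale (0.00251, 0.0190, 0.0317 and 0.0321). The main scale was set over the miRNA families themselves, so it cannot show a shift shared by most of them. The pollen miRNA miR845 changed by −0.70 ± 0.333, which passed only adjusted over the list alone. Of families 47 passed with lane as a covariate, against 48.

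**Figure D4:**
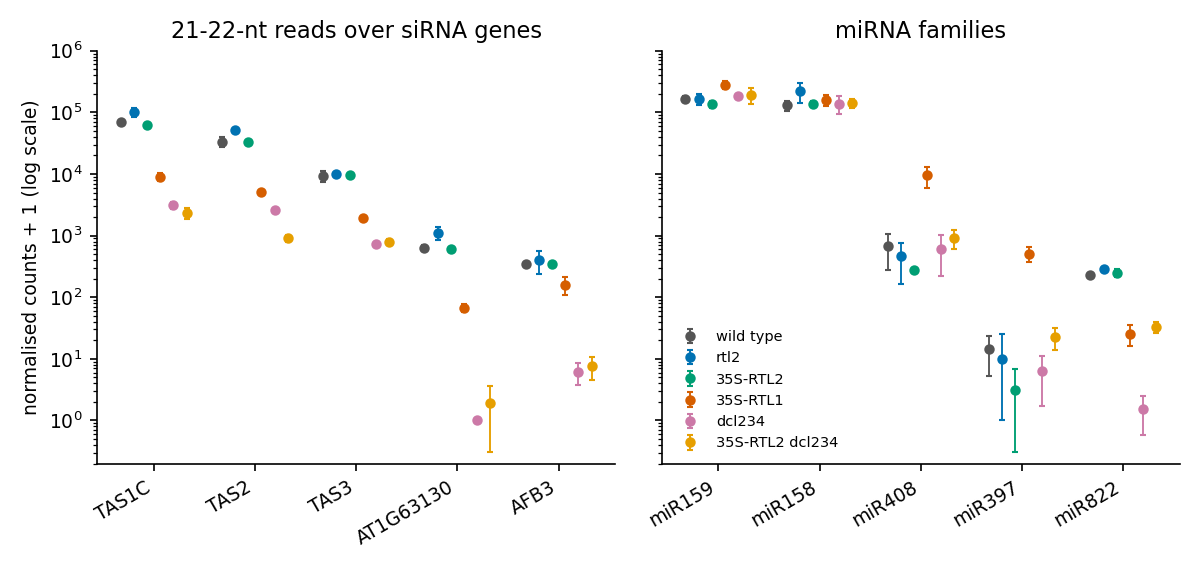
Normalised counts plus 1 (log scale; points are means, bars the SD, with lower arms shortened where the SD exceeded 0.9 of the mean) of 5 siRNA-making genes and 5 miRNA families in the 6 groups. TAS1C falls from 68760 counts in wild type to 9051 in 35S-RTL1 and 3099 in dcl234, while miR159 is at 165600 in wild type, 279900 in 35S-RTL1 and 182100 in dcl234.

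Loss of DCL2, DCL3 and DCL4 was compared with wild type to measure what these enzymes make in flowers. In dcl234, 24-nt reads fell to 0 counts in all 3 libraries in the most changed window of several loci. At ATCTH (AT2G25900, with AT2G25905 and AT2G25910, chromosome 2, 11043001–11049000) that window fell from 2107 ± 284 (SD, n = 3), at least 2930-fold. The most changed window at AT2G16580 (an auxin-responsive SAUR-type gene, with AT2G16575, chromosome 2, 7182501–7185500) fell from 1939 ± 166, at least 2690-fold. Those at AT3G16930 (chromosome 3, 5778501–5781500) and AT5G22860 (chromosome 5, 7639001–7642000) fell at least 1810-fold and 1610-fold. In 35S-RTL1 the same windows held 6803 ± 310, 4314 ± 444, 3179 ± 349 and 2855 ± 487 counts. The largest of 27 rises were in AT3G28715 (chromosome 3, 10777501–10778000), from 0 to 234 ± 56.7, at least 166-fold, and in AT5G43550 (chromosome 5, 17498001–17498500), from 0 to 87.3 ± 14.1, at least 61.9-fold. The next largest were between genes on chromosome 5 at 2656001–2656500, 131 nt from AT5G08250, from 0 to 53.3 ± 25, at least 37.8-fold, and at MIR319b (chromosome 5, 16660501–16661000), by log2 3.92 ± 0.375 (SE). Of 18004 windows 27 rose, 17677 fell and 300 did not pass, with a median of −4.52, or −4.24 with the 3685 windows at 0 at their bound. Falls passed in pericentromeric (4 rose, 8917 fell, median −4.46) and arm windows (23 rose, 8760 fell, median −4.58), in windows over protein-coding genes (12 rose, 3467 fell) and intergenic windows (7 rose, 10034 fell), and at all 8 windows of RdDM-regulated genes. With TMM over the windows 678 rose and 2466 fell (median −0.71), with DESeq2 831 and 3749 (median −0.82), and with total reads 178 and 15363 (median −2.68). With lane as a covariate 17665 windows passed, against 17704, and in a fit of only these groups 11066. As signs of RNA quality, reads outside 18–26 nt were 27.6% ± 13.1 in wild type and 46.9% ± 8.40 in dcl234, and chloroplast reads 2.57% ± 1.83 and 5.69% ± 1.83 (p = 0.2 each, exact permutation test, ranges overlapping). Mitochondrial reads were 1.15% ± 0.166 and 2.79% ± 0.492, without overlap (p = 0.10, exact permutation test).

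The ta-siRNA loci lost most of their 21–22-nt reads in dcl234. TAS1C fell by log2 4.47 (SE 0.233; n = 3 each) to 3099 ± 372 counts, TAS2 changed by −3.71 ± 0.209, TAS1A by −4.61 ± 0.242 and TAS3 by −3.69 ± 0.220, and all 7 tested fell (fry adjusted p 4.06e-11; adjusted p = 0.0776 with an estimated correlation). All 13 PPR/TPR siRNA genes fell, AT1G63130 from 625 ± 67.9 to 0, at least 867-fold, and AT1G63150 from 478 ± 73.8 to 0, at least 664-fold. Their median was −8.47, or −5.95 at the bound (fry adjusted p 9.50e-10; adjusted p = 0.0821 with an estimated correlation). All 6 other miRNA-triggered siRNA genes fell, among them AFB3 (−5.99 ± 0.409), AFB2 (−6.03 ± 0.485) and AT5G43740 (−5.49 ± 0.388; fry adjusted p 1.14e-08, adjusted p = 0.1296 with an estimated correlation). Of the small RNA pathway genes AGO1 (−6.42 ± 0.712) and DCL1 (−1.004 ± 0.415) fell, 1 of them adjusted over the list alone, with AGO2 at −0.14 ± 0.239. For this list fry gave an adjusted p of 0.000318 downward (adjusted p = 0.991 with an estimated correlation) but 0.0272 upward with total reads as the scale, and for the RdDM-regulated windows 3.58e-09 (adjusted p = 0.991 with an estimated correlation). Reads over AT2G16580 (871 ± 118 to 0, at least 1210-fold) and AT2G16575 inside it (at least 929-fold) fell. They rose over AT1G27535 (chromosome 1, 9564726–9565134) by 3.27 ± 0.259, from 127 ± 24.2 to 1223 ± 397, the RNA gene AT5G00525 by 2.84 ± 0.569, the pseudogene AT2G03650 by 2.82 ± 0.329 and AT2G28620 (overlapping MIR5637) by 2.77 ± 0.423. Of 1313 genes 135 rose, 532 fell and 646 did not pass (median −0.87, or −0.86 at the bound). With total reads as the scale the balance turned over, with 592 rising and 215 falling (median 1.02), and TMM over genes gave 233 and 405 (median −0.30); DESeq2 moved the median to −0.65. Of genes 638 passed with lane as a covariate and 395 with at least 4 reads, against 667.

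Few miRNA families passed in dcl234. Of 3 DCL4-made miRNAs 2 fell: miR822 changed by log2 −8.09 ± 0.474 (SE), from 226 ± 17.2 to 0.562 ± 0.973 counts, and miR839 went from 157.1 ± 34.4 to 0, at least 218-fold (fry adjusted p 3.58e-09; adjusted p = 0.0335 with an estimated correlation). The third, miR869, was at −0.19 ± 0.438. Falls also passed for miR840 (−4.92 ± 0.295), which rose to 1141 ± 66.3 in 35S-RTL1, and for miR868 (−1.16 ± 0.293; 0.72 with total reads as the scale). The largest rises were of miR3933 (1.96 ± 0.368), miR5012 (1.57 ± 0.286), miR851 (1.16 ± 0.222) and miR391 (1.13 ± 0.362, adjusted p 0.0307 by edgeR's quasi-likelihood test). The call of miR391 was lost with exact mature sequences (adjusted p 0.112), with DESeq2 (0.0519), and without wild type replicate 2 (0.121) or 3 (0.0651) or dcl234 replicate 1 (0.102) or 3 (0.0721). That of miR868 was lost without wild type replicate 2 (0.0654). Of 100 families 13 rose, 7 fell and 80 did not pass (median 0.10); DESeq2 gave 9 and 11, and total reads as the scale raised 88 and lowered 4 (median 2.04). The conserved miRNAs had 2 rises (miR393 and miR398; 1 adjusted over the list alone), the young miRNAs 2 rises and 3 falls (median 0.11, with the test downward), phosphate-starvation miRNAs 1 rise (miR2111, 1.79 ± 0.427), copper-responsive miRNAs 1 rise (miR398, 1.05 ± 0.333; list median −0.13 with the test upward), flower development miRNAs 0 of 8, and siRNA-trigger miRNAs 1 rise (miR393, 1.00 ± 0.278). None of these 6 lists passed by fry (adjusted p 0.208–0.796), and all moved up with total reads as the scale. Here too the main scale, set over the families, cannot show a shift shared by most miRNAs. The pollen miRNA miR845 fell by 1.02 on the log2 scale (SE 0.294), from 9437 ± 680 to 4663 ± 2090. Of families 18 passed with lane as a covariate and 13 without wild type replicate 2, against 20.

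The 35S-RTL2_dcl234 line was compared with dcl234 to see which small RNAs differ with the RTL2 construct in the absence of those Dicers. Over AP2 (AT4G36920, chromosome 4, 17400610–17403469), the floral homeotic gene targeted by miR172, 21–22-nt reads fell from 190 ± 79.1 (SD, n = 3) to 2.99 ± 2.86 counts, a log2 change of −5.87 ± 0.529 (SE). Over TAS1B (AT1G50055, overlapping MIR5636) they changed by −2.52 ± 0.246, over TAS2 by −1.50 ± 0.192 and over TAS3b by −1.09 ± 0.253, the 3 of 7 ta-siRNA loci that fell (list median −0.40; fry adjusted p 0.00164, adjusted p = 0.359 with an estimated correlation), while TAS1C was at −0.40 ± 0.203. The pseudogenes AT4G04250 (−1.65 ± 0.363) and AT3G30110 (−1.50 ± 0.237, overlapping MIR8183) fell. RTL2 itself (4.87 ± 0.641) and AT2G05294 (1.51 ± 0.349) rose. The call of AT2G05294 was lost without any 1 of 5 libraries, all of those compared but 35S-RTL2_dcl234 replicate 3 (adjusted p 0.0633–0.097). That of AT4G04250 was lost without 35S-RTL2_dcl234 replicate 1 or 3 or dcl234 replicate 1 or 3 (0.0531–0.0949), and with at least 4 reads per sequence (0.0532). Of 3 DCL4-made miRNAs miR822 rose by 5.24 ± 0.516, from 0.562 ± 0.973 to 31.5 ± 6.41 (fry adjusted p 0.00035; adjusted p = 0.131 with an estimated correlation; list median 2.90, or 0.40 at the bound). The other families called were miR8183 (−1.71 ± 0.258) and miR843 (−1.84 ± 0.460); of 100 families 1 rose, 2 fell and 97 did not pass. Reads of 24 nt rose over RTL2 and CPK9 (chromosome 3, 7119001–7121000) from 0 to 52.5 ± 28.9, at least 72.8-fold. They also rose in TAS3 (chromosome 3, 5862001–5862500) by 1.86 ± 0.259, from 178 ± 11.3 to 648 ± 50.7, in AT1G09805 (chromosome 1, 24721001–24721500) by 2.03 ± 0.316 and in AT3G06365 (chromosome 3, 14202001–14202500) by 1.43 ± 0.443, a call lost in 1000-nt windows (adjusted p 0.565), with at least 4 reads (0.105), and without 35S-RTL2_dcl234 replicate 3 (0.0523) or dcl234 replicate 2 (0.0827) or 3 (0.114). They fell to 0 at 131 nt from AT5G08250 (chromosome 5, 2656001–2656500) from 53.3 ± 25, at least 67.3-fold, and changed by −6.52 ± 0.618 near CBL8 (chromosome 1, 23946501–23947500), −6.49 ± 0.584 in AT2G04830 (chromosome 2, 1695501–1696000) and −6.21 ± 0.609 on chromosome 1 at 22890501–22891000. Of 18004 windows 43 rose, 3536 fell and 14425 did not pass (median −1.11, or −0.37 with the 7815 windows at 0 at their bound), and 515 rose and 860 fell with DESeq2 (median −0.05; −0.34 with TMM over the windows). Of 1313 genes 6 rose, 22 fell and 1285 did not pass (14 and 24 with DESeq2, which moved the median from −0.11 to 0.04). With lane as a covariate 3127 windows, 21 genes and 3 families passed, against 3579, 28 and 3. Windows numbered 1964 without 35S-RTL2_dcl234 replicate 3, 1349 in a fit of only these groups and 2059 with at least 4 reads, and genes 12 without dcl234 replicate 3, 14 without dcl234 replicate 1, 15 without 35S-RTL2_dcl234 replicate 3 and 16 in a fit of only these groups. Signs of RNA quality were compared as well: chloroplast reads were 5.69% ± 1.83 in dcl234 and 11.65% ± 4.76 in 35S-RTL2_dcl234 (p = 0.2, exact permutation test, ranges overlapping), and reads outside 18–26 nt 46.9% ± 8.40 and 51.7% ± 10.6 (p = 0.5, overlapping). All 24-nt reads of the tables began with A more often than 25–26-nt reads by 13.5 to 17.4 percentage points in dcl234, and by −3.1 to 1.3 in 35S-RTL2_dcl234.

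Falls in 35S-RTL2_dcl234 were spread over pericentromeric windows (9 rose, 1511 fell), arm windows (34 rose, 2025 fell), windows over protein-coding genes (17 rose, 736 fell) and intergenic windows (12 rose, 2230 fell). For these lists fry gave adjusted p of 0.00383, 0.00247, 0.00383 and 0.00202. Camera, which compares a list with the other windows, gave adjusted p = 0.877, 0.877, 0.998 and 0.877 with an estimated correlation. It does not pass a fall shared by most windows. Among small RNA pathway genes only RTL2 rose (fry adjusted p 0.0686), and among young miRNAs only miR843 fell, while the PPR/TPR genes, other triggered genes, RdDM-regulated windows and the conserved, phosphate-starvation, copper-responsive, flower development and siRNA-trigger miRNAs had no member past the rate by edgeR (fry adjusted p 0.347–0.787; miR845 at −0.36 ± 0.292). The other triggered genes had a median of −0.18 with the test upward, and the conserved miRNAs a median of −0.01 and a mean of 0.06 with the test downward.

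The rtl2 mutant was compared with wild type to ask which small RNAs depend on RTL2. In rtl2, 24-nt reads were gained from 0 at single windows: 131 nt from AT5G08250 (chromosome 5, 2656001–2656500) to 1619 ± 402 (SD, n = 3), at least 1150-fold, and in AT3G28715 (chromosome 3, 10777501–10778000) to 1431 ± 217, at least 1010-fold. Others arose 196 nt from AT1G08523 (chromosome 1, 23076501–23077000), at least 308-fold but not passing with DESeq2 (log2 10.52, adjusted p 0.542), and in AT1G14780 (chromosome 1, 5091501–5092000), at least 251-fold. They were lost in AT5G02330 (chromosome 5, 486501–487500) from 3261 ± 600 to 0, at least 2540-fold, and in NLP1 (AT2G27450, of polyamine synthesis; chromosome 2, 11739501–11740500) from 2224 ± 177 to 0, at least 1730-fold. Others were lost on chromosome 2 at 12773501–12774000, at least 432-fold, and 142 nt from PGR5 (chromosome 2, 2082001–2082500), at least 268-fold. In 35S-RTL2 the window in NLP1 held 2481 ± 200 counts. The young miRNA miR843 rose by log2 2.62 ± 0.401 (SE), from 30.9 ± 7.09 to 188 ± 47.9, the only call among 100 families (adjusted p 0.000272, edgeR's quasi-likelihood test). Among genes AT5G41765 (chromosome 5, 16716552–16717558) rose by 2.04 ± 0.415 and the pseudogene AT3G29540 (chromosome 3, 11354327–11354735) fell by 2.13 on the log2 scale (SE 0.461; edgeR adjusted p 0.023 and 0.0313). Both calls were lost with lane as a covariate (adjusted p 0.0526 and 0.0821), in a fit of only these groups (0.225 and 0.0661), with at least 4 reads (0.383 and 0.107), and without wild type replicate 2 (0.0618 and 0.106) or 3 (0.109 and 0.103) or rtl2 replicate 1 (0.0986 and 0.148) or 3 (0.168 and 0.168). The second was also lost without rtl2 replicate 2 (0.182). Of 18004 windows 200 rose, 167 fell and 17637 did not pass (331 passed with lane as a covariate; median 0.18, moved to 0.06 by total reads and 0.04 by TMM over the windows). Of 1313 genes 3 rose, 4 fell and 1306 did not pass (106 at an unadjusted p of 0.05; median 0.25, moved to 0.01 by TMM over genes), and DESeq2 gave 2 and 11. A lane covariate left 4 genes and 1 family. Genes numbered 0 without rtl2 replicate 3, in a fit of only these groups and with at least 4 reads, 1 without wild type replicate 2, 3 without wild type replicate 3 or rtl2 replicate 1, and 35 without the filter. Windows numbered 229 without rtl2 replicate 2 and 165 with at least 4 reads.

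Of 3 lists of siRNA-making genes, 2 tested upward in rtl2. Of 13 PPR/TPR siRNA genes none passed over all genes by edgeR, but 7 rose adjusted over the list alone, with AT1G63130 at log2 0.82 ± 0.321 (SE) and AT1G63150 at 0.73 ± 0.292 (list median 0.82; fry adjusted p 0.00602, 0.0219 with total reads as the scale, adjusted p = 0.144 with an estimated correlation). Of 7 ta-siRNA loci 0 passed over all genes and 2 adjusted over the list alone, with TAS1C at 0.56 ± 0.203 and TAS2 at 0.61 ± 0.188 (list median 0.49; fry adjusted p 0.0222, 0.624 with total reads as the scale, adjusted p = 0.464 with an estimated correlation). The other miRNA-triggered siRNA genes had no call and a median of 0.23, against 0.25 over all genes (fry adjusted p 0.480). Of windows 59 rose and 49 fell in pericentromeres, 141 and 118 in arms, 59 and 63 over protein-coding genes and 120 and 71 between genes. The young miRNAs had 1 rise, miR843, and the other lists had no member past the rate by edgeR, over all features or over the list alone (fry adjusted p 0.480–0.960 for all these lists; miR845 at 0.37 ± 0.292). With total reads as the scale the pathway genes, flower development and siRNA-trigger miRNAs turned from upward to downward, none past the rate.

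The 35S-RTL2 line was compared with wild type to ask which small RNAs differ with the RTL2 construct; RTL2 dose itself was not measured. Reads of 24 nt rose over CPK9 (AT3G20410, a calcium-dependent protein kinase gene) and RTL2 (chromosome 3, 7118501–7121000) from 0 to 10100 ± 751 (SD, n = 3), at least 7160-fold. They rose 131 nt from AT5G08250 to 2013 ± 158, at least 1430-fold, in AT3G28715 to 1413 ± 162, at least 1000-fold, and on chromosome 3 at 18459001–18459500 to 1100 ± 110, at least 780-fold. They fell to 0 near AT1G30670 (chromosome 1, 10880501–10881000) from 710 ± 46.4, at least 567-fold. They did so near DMS11 (chromosome 1, 6594001–6594500), at least 462-fold, near AT4G18650 (chromosome 4, 10265501–10267000), at least 350-fold, and in AT4G05240 (chromosome 4, 2688001–2688500), at least 247-fold, a window at 0 in rtl2 too. Reads of 21–22 nt rose over RTL2 by log2 15.18 ± 0.872 (SE), over the neighbouring CPK9 from 0 to 503 ± 19.4, at least 356-fold, and over AT1G27535 by 1.99 ± 0.248. They fell over AT3G57480 (chromosome 3, 21277270–21279404) from 52.8 ± 14.3 to 0, at least 42.2-fold, a call lost with at least 4 reads (adjusted p 0.252), and over the lncRNA gene AT3G07775 (overlapping AT3G47540; log2 −3.62 ± 0.529). Of 18004 windows 79 rose, 137 fell and 17788 did not pass (median 0.06), and of 1313 genes 3 rose, 3 fell and 1307 did not pass (92 at an unadjusted p of 0.05; median 0.11). No miRNA family passed by edgeR (10 at an unadjusted p of 0.05), and DESeq2 called 1. A lane covariate left 210 windows, 5 genes and 0 families, against 216, 6 and 0. Windows numbered 140 without 35S-RTL2 replicate 2 and 96 with at least 4 reads, and genes 11 and 12 without wild type replicate 2 and 3, 10 with DESeq2 and 42 without the filter. Of small RNA pathway genes only RTL2 rose (list median 0.06, mean 3.802; fry adjusted p 8.09e-05, adjusted p = 0.172 with an estimated correlation). Among RdDM-regulated windows 1 fell and among phosphate-starvation miRNAs 1 rose, miR2111, adjusted over the list alone (fry adjusted p 0.868 and 0.273). Pericentromeric windows had 24 rises and 39 falls, arm windows 55 and 98, windows over protein-coding genes 32 and 47, and intergenic windows 38 and 66. The other lists had no call (fry adjusted p 0.703–0.981 for all these lists; miR845 at 0.27 ± 0.292), with TAS1C at −0.12 ± 0.202 and AT1G63130 at −0.05 ± 0.32. The test ran against the median for PPR/TPR genes (median −0.03), other triggered genes (0.00) and RdDM-regulated windows (0.03, mean −0.31). With total reads as the scale the PPR/TPR genes, young miRNAs and arm, protein-coding and intergenic windows turned downward, none past the rate.

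Windows changed in both rtl2 and 35S-RTL2 mostly went the same way against wild type. Of 86 windows called in both comparisons, 43 were higher in both lines, 31 lower in both and 12 went opposite ways, where independent lists of those sizes would share 0.878, 1.27 and 2.25. The windows near AT5G08250 and in AT3G28715 were among 16 gained in both that held 0 reads in wild type. Both comparisons use the same 3 wild-type libraries, so part of the excess may come from the shared controls, which could not be split with enough libraries on each side. In 20 simulations without any change neither comparison had a call, so they do not tell how many joint calls shared controls add. The covariance of changes was 0.273 against 0.110 simulated, and their correlation was lower than simulated, 0.356 against 0.514.

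The difference of 35S-RTL2 from its control was not the same in dcl234 as in wild-type background at many loci. Near AT5G08250 (chromosome 5, 2656001–2656500), 24-nt reads rose from 0 to 2013 ± 158 (SD, n = 3) in the wild-type background and fell from 53.3 ± 25 to 0 in dcl234, a ratio of folds of at least 96100. The ratio was at least 8810 on chromosome 3 at 18459001–18459500 and at least 3170 in AT4G11790 (chromosome 4, 7090001–7090500), both also relatively lower in dcl234. All 3 windows held 0 reads in wild type and were also gained in rtl2, at 1619 ± 402, 309 ± 92.3 and 247.5 ± 140 counts, so these ratios rest on the wild-type libraries as much as on 35S-RTL2. It was at least 1220 near AT1G30670, 732 near AT4G18650 and 66.1 near DMS11, where reads fell to 0 in wild-type background only. For 21–22-nt reads AP2 had a difference of log2 changes of −6.11 ± 0.676 (SE), RTL2 −10.31 ± 1.089 and AT4G10603 4.82 ± 1.026, with bounds of 15.8-fold upward for MIF2 (AT3G28917) and 14.0-fold downward for ARF4 (AT5G60450, an auxin response factor targeted by TAS3 siRNAs). The call of AT4G10603 was lost with lane as a covariate (adjusted p 0.0815), with at least 4 reads (0.237) and without wild type replicate 2 (0.0879) or 35S-RTL2 replicate 1 (0.0614) or 2 (0.0799). With at least 4 reads the calls of MIF2 (0.259) and the window near DMS11 (1.00) were lost. Among miRNAs miR822 differed by 5.11 ± 0.609, the only one of 100. Of windows 69 were relatively higher in dcl234, 2870 lower and 15065 did not pass (118 and 677 with TMM over the windows, 362 and 712 with DESeq2, which moved the median from −1.23 to −0.55 and −0.03). Of genes 2 were higher and 10 lower, with 1301 not passing (6 and 9 with TMM over genes, 11 and 12 with DESeq2, medians −0.06 and 0.09 against −0.31). With lane as a covariate 2239 windows, 10 genes and 1 family passed. Windows numbered 1702 without 35S-RTL2_dcl234 replicate 3 and 1459 with at least 4 reads, and without the filter 35 genes and 2 families passed. The ta-siRNA loci had 2 falls (TAS1B and TAS2; 3 adjusted over the list alone; fry adjusted p 0.00499, adjusted p = 0.317 with an estimated correlation) and the DCL4-made miRNAs 1 rise, miR822 (fry adjusted p 0.000331; adjusted p = 0.0491 with an estimated correlation). The small RNA pathway genes had 1 fall, RTL2 (fry adjusted p 0.00413; adjusted p = 0.317 with an estimated correlation). Pericentromeric windows had 12 rises and 1243 falls, arm windows 57 and 1627, windows over protein-coding genes 19 and 593 and intergenic windows 20 and 1820 (fry adjusted p 0.00571, 0.00499, 0.00571 and 0.00413; adjusted p = 0.905, 0.905, 0.981 and 0.894 with an estimated correlation). Copper-responsive miRNAs passed at 2 of 3 adjusted over the list alone (fry adjusted p 0.0911), and the other lists had no call (fry adjusted p 0.0808–0.987; miR845 at −0.63 ± 0.413). The other triggered genes had a median of −0.15 with the test upward, and with total reads as the scale the ta-siRNA loci no longer passed (fry adjusted p 0.0940).

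The lines with the RTL1 and RTL2 constructs were compared with each other. Of miRNAs, miR8170 was higher in 35S-RTL1 than in 35S-RTL2 by log2 9.10 ± 0.777 (SE; n = 2 against 3), miR397 by 8.11 ± 1.076, miR408 by 5.11 ± 0.637 and miR398 by 4.04 ± 0.354. Lower were miR826 (−3.74 ± 0.454), miR822 (−3.30 ± 0.370), miR824 (−2.58 ± 0.300) and miR858 (−2.53 ± 0.343). Reads of 21–22 nt were higher over ENT6 (6.37 ± 0.861), AT2G47020 (4.78 ± 0.603, a gene that overlaps MIR408), AT5G55350 (4.04 ± 0.646) and AT1G12665 (3.71 ± 0.595), and lower over RTL2 (−16.30 ± 1.097), CPK9 (at least 366-fold) and the lncRNA genes AT2G09610 (at least 125-fold; overlapping AT2G45380) and AT1G07493 (at least 107-fold). Reads of 24 nt were higher near AT4G18650 (0 against 125 ± 4.32, at least 99.9-fold), in AT2G25905 (chromosome 2, 11045501–11048000; log2 7.58 ± 0.599) and on chromosome 4 at 926001–927500 (6.90 ± 0.958) and 5735001–5735500 (6.70 ± 0.761). They were at 0 in 35S-RTL1 over CPK9 and RTL2 (at least 7360-fold lower), near AT5G08250 (1470-fold), in UBP6 (1110-fold) and in GH9B12 (958-fold). Of 18004 windows 438 were higher, 15139 lower and 2427 did not pass (median −4.03, or −3.41 at the bound; 4154 and 5947 with TMM over the windows, median −1.05, and 4137 and 6685 with DESeq2, median −1.22; median −3.28 with total reads). Of 1313 genes 54 were higher, 775 lower and 484 did not pass (median −1.78, or −1.69 at the bound; 147 and 570 with total reads, median −1.03, 151 and 570 with TMM over genes, median −0.98, and 201 and 531 with DESeq2, median −0.78). Of 100 families 23 were higher and 30 lower (37 and 13 with total reads as the scale, which moved the median from −0.36 to 0.40). With lane as a covariate 14828 windows, 768 genes and 46 families passed, against 15577, 829 and 53, and 369 genes with at least 4 reads. Chloroplast reads were 3.75% ± 0.0161 in 35S-RTL1 and 1.57% ± 0.452 in 35S-RTL2, without overlap (p = 0.10, exact permutation test). Reads of snRNA and snoRNA genes were 1.49% ± 0.397 and 0.724% ± 0.0776, also without overlap (p = 0.10, exact permutation test).

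Lists that were lower in 35S-RTL1 than in 35S-RTL2 were the ta-siRNA loci (7 of 7; TAS1C −2.80 ± 0.254; fry adjusted p 1.45e-09, adjusted p = 0.319 with an estimated correlation). So were PPR/TPR siRNA genes (12 of 13; fry adjusted p 7.93e-08, adjusted p = 0.349 with an estimated correlation). Other triggered genes (3 of 6; fry adjusted p 0.000192, adjusted p = 0.953 with an estimated correlation) and small RNA pathway genes (4 of 4, with RTL2, the gene of the construct in 35S-RTL2, at −16.30 carrying the mean of −5.96, median −3.06; fry adjusted p 7.81e-09, adjusted p = 0.319 with an estimated correlation) were lower too. So were the RdDM-regulated windows (8 of 8; fry adjusted p 4.07e-08, adjusted p = 0.736 with an estimated correlation) and the DCL4-made miRNAs (2 of 3; fry adjusted p 4.41e-07, adjusted p = 0.319 with an estimated correlation). The copper-responsive miRNAs were higher, 3 of 3 (fry adjusted p 7.53e-06, adjusted p = 0.319 with an estimated correlation). Phosphate-starvation miRNAs had 2 higher, conserved miRNAs 7 higher and 6 lower, young miRNAs 7 and 12, flower development miRNAs 1 and 2 (1 and 1 adjusted over the list alone) and siRNA-trigger miRNAs 2 and 3, without passing by fry (adjusted p 0.0559, 0.0627, 0.104, 0.439 and 0.805) except upward with total reads as the scale, and miR845 was lower (−0.97 ± 0.336). The siRNA-trigger miRNAs had a median of −0.63 with the test upward. Pericentromeric windows were higher at 172 and lower at 7431, arm windows at 266 and 7708, windows over protein-coding genes at 142 and 2965 and intergenic windows at 234 and 8716. For these 4 window lists, and for the same lists in 35S-RTL1 and dcl234 against wild type, fry passed downward (adjusted p at most 4.93e-09, 8.32e-09 and 4.99e-11). Camera with an estimated correlation passed for none (adjusted p = 0.736, 0.771 and 0.991 at the lowest). It compares a list with the other windows, so it does not pass a fall shared by most of them.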

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

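The difference of changes and the values of the library in no group were planned, and the regroupings of libraries below were chosen after the results were seen. Between both backgrounds the change made by 35S-RTL2 differed at 2939 windows, 12 genes and 1 miRNA family (n = 3 libraries in each of 4 groups, edgeR's quasi-likelihood test at a false discovery rate of 0.05). Relative to wild-type background, the largest windows lower in dcl234 lay near AT5G08250 (ratio of folds at least 96100), near AT3G49765 (at least 8810) and in AT4G11790 (at least 3170). All 3 held 0 reads in wild type and were also gained in rtl2 (1619, 309 and 247.5 counts), so the wild-type libraries carry these ratios as much as 35S-RTL2 does. Those relatively higher lay near AT1G30670 (at least 1220), AT4G18650 (at least 732) and DMS11 (at least 66.1). Among genes the differences of log2 changes were −10.31 for RTL2, −6.11 for AP2 and 4.82 for AT4G10603, with bounds of 15.8 for MIF2 (higher) and 14.0 for ARF4 (lower). With at least 4 reads per sequence DMS11, AT4G10603 and MIF2 no longer passed (adjusted p 1.00, 0.237 and 0.259). For miR822 the difference was 5.11.

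Libraries were also regrouped, the real split counted among the splits. For the difference of changes libraries were regrouped within each background, in 100 splits drawn at random. As many calls as the real 2939 windows came from 1 of them (highest other 2685), as many as the 12 genes from 2 (highest other 12) and as many as the 1 family from 11 (highest other 3). Such splits ask whether 35S-RTL2 has no effect in either background, and those with 2685 windows and 12 genes kept the real groups in dcl234 background, so they do not tell whether the difference arose by chance. Each other comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05. In rtl2 the real grouping gave 367 windows, 7 genes and 1 family and the highest other split 17, 11 and 2, and 1, 2 and 2 splits gave as many. In 35S-RTL2 these were 216, 6 and 0 against 1, 0 and 0, with 1, 1 and 10 splits. In dcl234 they were 17704, 667 and 20 against 0, 0 and 0, with 1 split each, and in 35S-RTL2_dcl234 3579, 28 and 3 against 12, 0 and 1, with 1 split each. With 2 libraries of 35S-RTL1 no such splits were counted.

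The library in no group, whose title and genotype label name different constructs, held 0 reads over RTL1 and RTL2. Both its title and its genotype label name dcl234. The 24-nt share of this library was 8.18% and its 21-nt share 48.4% (n = 1), against means of 12.1% and 46.7% in dcl234. It held more of miR391 (1410.27 normalised counts) than any other library (highest 637.05; highest wild type 247.84), and more 21–22-nt reads over AT3G07855 (3215.59; highest of the others 3025.54, of wild type 693.08) and AT1G62760 (114.75; 64.82 and 16.63). Reads of 23–24 nt stood at 5210.99 at MIR319a (AT4G23713; 3697.81 and 271.97) and 517.68 at MIR319b (AT5G41663; 426.15 and 28.51), so for AT3G07855 and both MIR319 genes most of the excess over wild type was shared with other groups. With a single library these values have no error, and 9.17% of its reads came from snRNA and snoRNA genes.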

How the results depend on the processing

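Libraries with fewer reads limit what is called at sparse loci, and sequences read once are missing. With 1 library of 35S-RTL1 left out, the other is assumed to vary like the rest. The alternatives with at least 4 reads per sequence, and all counts without Col_wild_type replicate 1, were chosen after seeing the data, and the others before. A list of transposon windows was not run for want of annotation. Of counts of calls, 171 stayed within a factor of 1.5 and 39 moved over all settings other than leaving out libraries. Among the former are counts split over matching places, which could hardly move, since practically all sequences matched a single place. The cause was not tested except where stated.

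With TMM over the windows the calls were 3144 in dcl234, 1011 in 35S-RTL2_dcl234, 795 for the difference of changes and 10101 for 35S-RTL1 against 35S-RTL2, since that scale takes most windows as unchanged. DESeq2 gave 4580, 1375 and 1074 windows for the first 3 of these, 13 genes in rtl2, 10 in 35S-RTL2 and 23 for the difference of changes, and 1 miRNA family in 35S-RTL2. Fits of only the groups compared gave 11066 windows in dcl234, 1349 in 35S-RTL2_dcl234, and 0 genes in rtl2, 435 in 35S-RTL1 and 16 in 35S-RTL2_dcl234. With at least 4 reads there were 165 windows in rtl2, 96 in 35S-RTL2, 2059 in 35S-RTL2_dcl234 and 1459 for the difference of changes, and 0 genes in rtl2, 355 in 35S-RTL1, 395 in dcl234 and 369 for 35S-RTL1 against 35S-RTL2. Without the filter there were 35 genes in rtl2, 42 in 35S-RTL2 and 35 for the difference of changes, with 2 families. Lane as a covariate left 4 genes in rtl2. With the replicate block, windows numbered 444 in rtl2, 273 in 35S-RTL2, 15195 in 35S-RTL1, 17705 in dcl234 and 3628 in 35S-RTL2_dcl234, families 1 in rtl2 and 3 in 35S-RTL2_dcl234, and no count moved over 1.5-fold. Deviations of libraries with the same number had median correlations of 0.0385 for windows, 0.042 for genes and 0.1285 for families (22 of 40 pairs over 0.1). With different numbers these were −0.0225, −0.019 and −0.057. All 6 libraries were closest to their own number for windows and genes of 35S-RTL2 against wild type, where not every pair exceeded 0.1.

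With total reads as the scale 92 families passed in dcl234, miR868 turned to 0.72, the small RNA pathway genes tested upward in dcl234 (adjusted p 0.0272), and 1 list passed in rtl2 and 16 in dcl234. With camera and an estimated correlation 0 lists passed in rtl2, 35S-RTL2, 35S-RTL1, 35S-RTL2_dcl234 and 35S-RTL1 against 35S-RTL2, and 1 each in dcl234 and for the difference of changes. Camera compares a list with other features, so a change shared by most of them does not pass it. Leaving out structural and organelle reads turned the difference in 24-nt share of rtl2 to −0.944. With 20–22-nt reads DCL2 held 0.740 counts in 35S-RTL2_dcl234.

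Leaving out 1 library at a time gave 229–323 windows in rtl2 (229 without rtl2 replicate 2), 140–231 in 35S-RTL2 (140 without 35S-RTL2 replicate 2), 1964–3890 in 35S-RTL2_dcl234 and 1702–3407 for the difference of changes (1964 and 1702 without 35S-RTL2_dcl234 replicate 3). Genes numbered 0–7 in rtl2 (0 without rtl2 replicate 3), 4–12 in 35S-RTL2 (12 without Col_wild_type replicate 3) and 12–23 in 35S-RTL2_dcl234 (12 without dcl234 replicate 3). Families in dcl234 numbered 13–18 (13 without Col_wild_type replicate 2). Without Col_wild_type replicate 1, which held 5.18% snRNA and snoRNA reads, windows numbered 288 in rtl2, 155 in 35S-RTL2, 15057 in 35S-RTL1 and 17552 in dcl234. Differences in structural and organelle shares changed sign, in percentage points. In rtl2 they ran for rRNA from −0.0699 to 0.00231 and for snRNA and snoRNA from −2.04 to 0.255. In 35S-RTL2 they ran for rRNA from −0.0713 to 0.00092, tRNA −0.321 to 0.0289, snRNA and snoRNA −2.26 to 0.0345 and chloroplast −1.76 to 0.0149. In 35S-RTL1 they ran for rRNA from −0.011 to 0.0652, tRNA −0.117 to 0.533 and snRNA and snoRNA −1.50 to 0.802. In 35S-RTL2_dcl234 they ran for tRNA from −0.134 to 0.220, snRNA and snoRNA −0.314 to 0.787 and mitochondrial −0.679 to 0.0592, and for 35S-RTL1 against 35S-RTL2 mitochondrial −0.335 to 0.323.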

Other observations

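The tests on inverted repeats, sequences read once and RNA fragments were written before their results were seen, and those on doses of RTL2, wild-type plants, carry-over and mixed tissue after. The first pattern is that rtl2 and 35S-RTL2 differ from wild type at the same windows, such as those near AT5G08250 and in AT3G28715. If opposite doses of RTL2 were the cause, most windows called in both should go opposite ways, and 14.0% did. The shared wild-type libraries favour joint calls of one sign, and simulations without change gave no joint call to set this share against. The 12 windows that went opposite ways were above the 2.25 of independent lists. The share does not argue against a low dose in both lines, since RTL2 dose was not measured. The 191700 counts of 21–22-nt reads over RTL2 in 35S-RTL2 could mark silencing of the gene. If the wild-type plants instead stood apart, windows gained in both lines should be seen in dcl234 too, and 53.5% held at least 3 reads there, against 81.7% of uncalled windows of like abundance. Windows lost in both lines should then be missing in dcl234, but 51.6% held at least 3 reads, against 90.5% of uncalled windows. The shares of gained and lost windows lay close, so over the whole set of windows dcl234 does not decide. The windows near AT5G08250 and in AT3G28715 rose in dcl234 too, which goes with wild-type plants that stand apart. But the window near AT5G08250 held no reads in 35S-RTL2_dcl234 and 35S-RTL1, so wild type was not the only group without them. Both windows are examples picked from the largest changes. Wild-type plants that stand apart, which might reflect inherited differences between seed stocks, stay open. RTL2 mRNA levels and DNA methylation of these windows in the plants used could tell.

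The second pattern is that 24-nt reads were kept or raised at a minority of windows in 35S-RTL1 while most fell. The omission of sequences read once could deepen falls at sparse windows, but dcl234, with the same omission, differed by only 0.24 in median log2 change between windows of over 1000 and of 20 to 50 wild-type counts, against 3.27 in 35S-RTL1 (0.24 and 3.01 with windows at 0 at their bound). Inverted repeats, whose hairpins might escape the enzyme, lay within 3 kb of 2.43% of raised windows (exact 95% interval 1.26–4.21, n = 493) and 3.3% of fallen ones (Fisher's exact p = 0.366, two-sided). That test decides nothing, because the tables hold practically only sequences matching 1 place, so reads shared by both arms of a hairpin are missing, and inverted repeats stay open. The values for dcl234 argue against the omission of sequences read once as the main cause. Windows at 0 in dcl234 but raised in 35S-RTL1, such as that of ATCTH, might be made from precursors RTL1 does not cut, which was not tested here.

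The third pattern is that dcl234 retained 24-nt reads, 5.77% of the wild-type window counts. Carry-over between libraries of a lane would have put 1529 reads of 23–24 nt over RTL2 into the 3 dcl234 libraries, and 0 were found. Mixed-in wild-type tissue should have left as much of the PPR/TPR siRNAs, of which 1.14% was left. In the single dcl234 libraries this was 0.156, 0.16 and 0.287 of the 24-nt share left, where mixing as the whole cause needs 1. The ta-siRNA loci kept more. Their median log2 change was −3.69, against −5.95 for the PPR/TPR genes and −4.24 for the windows, both at the bound. Taken alone the ta-siRNA loci would allow mixing. Mixing sets only a lowest share for each siRNA, so the PPR/TPR genes limit it and the ta-siRNA loci do not. Fragments of longer RNA could not be told apart, since all 24-nt reads of the tables began with A more often than 25–26-nt reads by 13.5 percentage points in the lowest dcl234 library, between the limits set. Both lengths included organelle reads, which the windows do not hold. Outside organelles, structural RNA genes and miRNAs, 67.5% of 24-nt reads in dcl234 began with A, but 25–26-nt reads were not split in this way. Another enzyme, possibly DCL1, could make the rest, which was not tested here. Plants of dcl234 with reduced DCL1 could help to tell.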
